A study of Mus musculus with 24 samples.

How the data were processed

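Total RNA from mouse lung tissue was hybridised to Affymetrix MOE 430 2.0 arrays, per the labels. The 24 arrays comprised 14 tumour nodules, dissected by eye from bitransgenic animals fed doxycycline for 3 to 6 months, and 10 normal lungs from littermates that lacked the transgenes or carried 1 of them, also on doxycycline, per the labels. The labels give a group, a replicate number and a strain for each array, but not the animal, its sex, a batch or a date. They do not state that each array came from a separate mouse, so the p-values measure the spread between these samples.

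The deposited values are log2 probe set summaries that the authors made with RMA, per the submitters' processing notes. The RMA version and its settings are not given in the sources used here. The values had 2 decimals, and their quantiles were nearly the same in all 24 columns, so the arrays had been put on a common scale. No further normalization was applied. Array data hold no counts, so the precision was set by the spread between arrays and by their number per group, which was 4 or 5. The fit shares its estimate of the spread over all groups, although tumours varied more than normal lungs. The mean absolute difference between arrays reached 0.439 among T790M tumours and 0.187 among FVB normals.

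The table held 45101 probe sets. The 64 control probe sets were left out of the gene tests. The platform annotation assigned 1 gene to 34945 probe sets, several genes to 932 and none to 9160. Gene symbols were updated by Entrez identifier for 34741 probe sets, and 204 kept the older symbol. The gene order used for neighbours came from the RefSeq table of assembly GRCm38. Each of 18193 genes was represented by the probe set with the highest mean over all arrays; 9010 genes had several probe sets. The 10092 probe sets with no gene or several genes were tested apart.

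Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit with 5 group means, 19 residual degrees of freedom, eBayes with a trend). P-values were two-sided and adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. Each tumour group was compared with the normal lungs of its own strain label. L858R+T790M tumours were compared with T790M tumours directly, since both carry the label FVB. L858R tumours were compared with each of these after the matching normals had been subtracted from both, which is a test of the difference between tumour effects. The normal sets were compared with each other.

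The groups, the tests, the alternatives, the rule for naming genes and 41 gene lists were fixed before the data were examined. The rule named the 12 highest and 12 lowest log2 differences among called genes whose arrays did not overlap between the groups (no such condition for the strain-adjusted comparisons), clone and predicted names passed over, and any member of the lists. The lists covered cell types, tissues and pathways; 491 of their 523 entries were measured. Zfp874a and Nr1d1 in the comparison of normal lungs, Rian in L858R+T790M and Mirg in L858R and L858R+T790M tumours were chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, adjusted over the 41 lists. camera asks whether a list ranks apart from other genes, and fry whether its genes move one way on balance. Counts of list members are given over all genes tested and adjusted over the list alone. Single measures were compared by exact two-sided permutation tests.

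The alternatives were centring each array on its median, quantile normalization again, the median over the probe sets of a gene, every probe set, dropping the 6064 dimmest genes, array weights, no trend in eBayes, a fit to only the groups compared, the direct difference between tumour groups, all 10 normal lungs as 1 group, the replicate number as a block, a sex score as a covariate, an adjusted p under 0.01, a change of at least 2-fold, and leaving out each array. List counts without each array and under both scalings, and exact tests of all 41 list means in place of the proliferation lists alone, were added after the data were seen. The model was also tested on simulated data. With a log2 difference of 1 added to 100 genes between arrays of equal mean, 91 were called, and with a difference of 2, 99 of 100; 11 of 201 calls (5.47%) fell on unchanged genes. A shift of 0.5 in the mitosis list was called by camera with an adjusted p of 8.43e-23 and with 0 other lists. The simulated genes varied independently and with the same spread in every group. The simulation therefore does not test camera on lists of correlated genes, or groups of unequal spread.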

Results

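Gene expression was measured with 1 array per sample in 24 mouse lung samples. The tumours carried a mutant epidermal growth factor receptor (EGFR) transgene and formed 3 groups, with 4 L858R, 5 L858R+T790M and 5 T790M tumours. L858R is an activating change in the EGFR kinase domain, and T790M is a kinase change known from tumours that resist EGFR inhibitors. The 10 normal lungs formed 2 sets, 5 labelled FVB (FVB normals) and 5 labelled FVB mixed (mixed-strain normals). The L858R tumours shared the label FVB mixed and the other tumours the label FVB. Array medians lay between 7.2 and 7.3 on the log2 scale. Differences below are log2 values ± SE, and n is the number of arrays.

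The first principal component carried 58.1% of the variance and placed every normal lung at -43.2 or below and every tumour but 1 at 12.6 or above. The exception was T790M replicate 1, at -2.96. The component after it carried 8.63% and set apart L858R+T790M replicate 2 (22.6), T790M replicate 2 (31.5) and T790M replicate 4 (45.3) at one end, and L858R+T790M replicates 5 (-35.5) and 1 (-20.7) and L858R replicates 1 (-25.8) and 2 (-21.2) at the other. Correlations between arrays were 0.987 or above among FVB normals, 0.988 or above among mixed-strain normals, and as low as 0.975, 0.950 and 0.946 among L858R, L858R+T790M and T790M tumours.

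**Figure D1:**
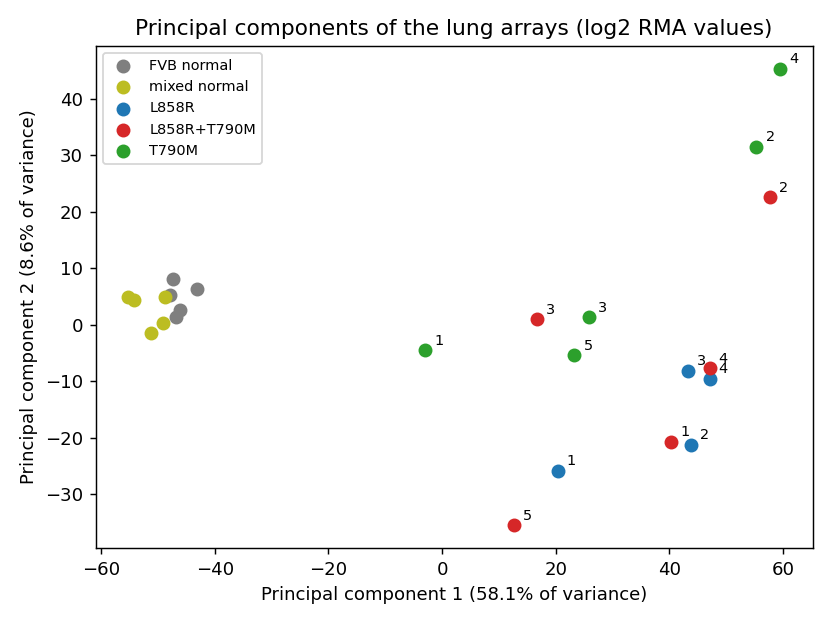
Each point is 1 array, placed by its scores on the first principal component (horizontal, 58.1% of the variance) and the next one (vertical, 8.63%), with colours for the 5 groups and replicate numbers beside the tumours. The normal lungs form a compact cluster on the left, T790M replicate 1 lies at -2.96 between them and the other tumours, and T790M replicate 4 reaches 59.5.

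The first comparison asked how L858R tumours (n = 4) differed from mixed-strain normals (n = 5). Epiregulin (Ereg), a ligand of EGFR, was 57.6-fold higher (5.85 ± 0.55). Kng1, which encodes the precursor of kinins, rose by 5.48 ± 0.67, Arg2, an arginase, by 4.90 ± 0.34, the imprinted gene Dlk1 by 5.69 ± 0.99 and the imprinted noncoding RNA Meg3 by 3.96 ± 0.27. The dimmer of the 2 Kng1 probe sets was not called. Tnfsf9 (4.48 ± 0.38), a ligand of the TNF family, and the tight junction gene Cldn2 (3.98 ± 0.70) rose too. Among the genes that fell were Ogn (-5.33 ± 0.93), a matrix proteoglycan, Tcf21 (-4.28 ± 0.62), a transcription factor of lung mesenchyme, and Hpgd (-4.55 ± 0.83), which degrades prostaglandins.

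Epithelial genes rose in L858R tumours: 12 of 15 alveolar type 2 markers (12 adjusted over the list alone) and 11 of 16 epithelial junction genes (11), with adjusted p = 0.296 with an estimated correlation for both. Cebpa rose by 1.56 ± 0.14, Nkx2-1 by 0.94 ± 0.14 and the keratin gene Krt18 by 1.95 ± 0.28. Sftpc, for surfactant protein C, differed by 0.05 ± 0.04 (adjusted p = 0.283), but with the median over its probe sets it fell (-0.37, adjusted p = 0.00721). Markers of other epithelial types fell: 9 of 12 for alveolar type 1 cells (10 adjusted over the list alone), 6 of 12 for club cells (6) and 12 of 13 for ciliated cells (12), with adjusted p from 0.296 to 0.391 with an estimated correlation. Aqp5 of the type 1 list rose by 1.02, a call lost without L858R replicate 2 (0.97, adjusted p = 0.0600) or mixed-strain normal replicate 3 (0.91, adjusted p = 0.0617).

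Markers of the lung's other compartments fell with them: 19 of 20 endothelial genes (19 adjusted over the list alone; Tek -3.56 ± 0.58), 13 of 14 fibroblast genes (13), 12 of 12 smooth muscle and pericyte genes (12) and 7 of 7 mesothelial genes (7), each with adjusted p = 0.296 with an estimated correlation. The mesothelial count was 4 without L858R replicate 1 or 3 or mixed-strain normal replicate 2, 3 or 5. Of the cardiac muscle genes 8 of 10 fell (8 adjusted over the list alone; adjusted p = 0.391 with an estimated correlation) while Myh7 rose by 1.56. Falls also met 7 of 12 T cell genes (7 adjusted over the list alone), 7 of 10 NK and cytotoxic genes (8) and 7 of 10 B cell genes (7; Ms4a1 -2.76 ± 0.49), with adjusted p from 0.296 to 0.416 with an estimated correlation. Macrophage markers went up: 10 of 13 alveolar macrophage genes (11 adjusted over the list alone; Marco 3.42 ± 0.55, a scavenger receptor) and 8 of 11 genes of lipid-associated and activated macrophages (8; Mmp12 3.44 ± 0.50, a matrix metalloproteinase), with adjusted p = 0.296 with an estimated correlation. Cidec (-1.10) and Apoe (-0.66) of these lists fell, but Apoe was not called without L858R replicate 2 (-0.46, adjusted p = 0.0814).

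Proliferation and signalling genes rose in the same tumours. The mitosis list had 19 of 23 genes up (19 adjusted over the list alone; Mki67 1.48 ± 0.39) and the DNA replication list 13 of 20 (14), with adjusted p = 0.391 and 0.416 with an estimated correlation. Of the EGFR family receptors and ligands 6 of 10 rose (7 adjusted over the list alone; Erbb3 1.18 ± 0.19, Btc 1.04 ± 0.24), and 12 of 17 ERK output genes (13; Dusp4 1.59 ± 0.28, Etv4 1.39 ± 0.24), both with adjusted p = 0.296 with an estimated correlation. Ier3 of the ERK list fell (-1.58 ± 0.25). Glycolysis (8 of 11 up, 8 adjusted over the list alone) and hypoxia genes (9 of 13 up, 9) rose with Hk2 (2.00 ± 0.27), a hexokinase, at adjusted p = 0.323 and 0.406 with an estimated correlation; Vegfa (-1.07 ± 0.14) and Pfkp (-0.58) fell. The call of Pfkp was lost without L858R replicate 1, 2 or 3 or mixed-strain normal replicate 1, 4 or 5 (-0.59 to -0.53). In limma 7523 of 18193 genes were called, 4235 higher and 3288 lower, 1966 of them by at least 2-fold. The arrays of the groups did not overlap for 6504 of all genes (35.8%, where chance gives 1.59%), 5924 of them called. The 3-prime minus 5-prime difference of the Gapdh control probe sets, a measure of RNA integrity, was 0.11 higher in the tumours (exact permutation p = 0.0317, adjusted p = 0.158 over 10 tests).

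L858R+T790M tumours (n = 5) were compared with FVB normals (n = 5). Kng1 was 122-fold higher (6.93 ± 0.63), Dlk1 87.8-fold (6.46 ± 0.94) and Ereg 86.0-fold (6.43 ± 0.52). Afp, the fetal serum protein alpha-fetoprotein, rose by 4.36 ± 0.47, the chemokine Cxcl3 by 3.98 ± 0.55, Meg3 by 4.02 ± 0.25 and Marco by 3.65 ± 0.52. Car3, a carbonic anhydrase of adipose and muscle tissue, fell most (-5.78 ± 0.76), with Hpgd (-5.11 ± 0.79), Tmem100 (-4.54 ± 0.78) and the fat hormone Adipoq (-4.11 ± 0.50).

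Of the alveolar type 2 markers 12 of 15 rose (13 adjusted over the list alone; Cebpa 1.71 ± 0.13) and of the epithelial junction genes 15 of 16 (15; Krt18 2.31 ± 0.26), with adjusted p = 0.207 and 0.153 with an estimated correlation. Club cell markers fell (10 of 12, 11 adjusted over the list alone; Cyp2f2 -4.04 ± 0.67), as did ciliated (12 of 13, 12), alveolar type 1 (7 of 12, 8), endothelial (20 of 20, 20; Tek -3.31 ± 0.54), fibroblast (10 of 14, 11), smooth muscle and pericyte (11 of 12, 12) and mesothelial markers (5 of 7, 6), with adjusted p from 0.177 to 0.554 with an estimated correlation. Aqp5 (1.03) and Cldn18 (0.58) of the type 1 list rose, Aqp5 with no call without L858R+T790M replicate 1 or FVB normal replicate 4 or 5 (0.90 to 0.93). Cardiac (8 of 10, 8 adjusted over the list alone), adipose (3 of 5, 3), T cell (9 of 12, 9), NK and cytotoxic (6 of 10, 7) and B cell genes (7 of 10, 7) fell too, with adjusted p from 0.177 to 0.397 with an estimated correlation, while Myh7 rose by 1.65. Lipid-associated and activated macrophage genes rose (6 of 11, 6 adjusted over the list alone; Arg1 3.08 ± 0.73; adjusted p = 0.223 with an estimated correlation). Among alveolar macrophage genes 3 of 13 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.458), and 8 rose without L858R+T790M replicate 2.

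EGFR family genes rose in L858R+T790M tumours (8 of 10, 8 adjusted over the list alone), with Hbegf (1.28 ± 0.19) and Epgn (0.88 ± 0.14), both EGFR ligands, beside Ereg. ERK output (14 of 17, 14 adjusted over the list alone; Dusp4 2.06 ± 0.26, Spred1 1.65 ± 0.17) and p53 target and senescence genes (9 of 12, 9; Cdkn1a 1.09 ± 0.16, a cell cycle inhibitor, Cdkn2b 0.82 ± 0.16) rose as well. These lists had adjusted p = 0.129, 0.177 and 0.177 with an estimated correlation. Glycolysis (8 of 11, 8 adjusted over the list alone) and hypoxia genes (8 of 13, 9; Egln3 3.01 ± 0.67) rose, with adjusted p = 0.177 and 0.238 with an estimated correlation, and Vegfa fell (-0.70). The mitosis list had 7 of 23 genes up (2 adjusted over the list alone; adjusted p = 0.621 with an estimated correlation). That count was 2 without L858R+T790M replicate 3 or 4 or FVB normal replicate 2, 3 without FVB normal replicate 5 and 4 without FVB normal replicate 1 or 4. DNA replication had 6 of 20 up (2 adjusted over the list alone; camera adjusted p = 0.0918), 2 without L858R+T790M replicate 3 or 4 or FVB normal replicate 1 or 2, and 10 without L858R+T790M replicate 2. Of 20 chemokines and cytokines 8 rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.168), with 3 up without L858R+T790M replicate 1. Their mean was 8.81 and 9.14 in L858R+T790M replicates 1 and 5, 7.57 to 8.01 in the other L858R+T790M tumours and 7.55 to 7.87 in FVB normals. The interferon response mean was likewise 9.35 and 11.24 in replicates 1 and 5, 7.35 to 8.17 in the others and 8.28 to 8.49 in FVB normals. In limma 6594 genes were called, 3671 higher and 2923 lower, 1536 by at least 2-fold, and 5417 of all genes had separate ranges (29.8%, chance 0.794%), 4910 of them called.

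T790M tumours (n = 5) were compared with the same FVB normals (n = 5). Kng1 rose by 5.30 ± 0.63, Dlk1 by 4.54 ± 0.94 and the imprinted noncoding RNAs Meg3, Rian and Mirg by 4.42 ± 0.25, 4.21 ± 0.52 and 3.88 ± 0.58. Kng1 and Dlk1 have 2 probe sets each, and the dimmer of each was not called. The receptor tyrosine kinase gene Ros1 rose by 3.54 ± 0.34 and Ereg by 3.30 ± 0.52, though T790M replicate 4 (5.74) lay below the highest FVB normal (6.09). Hpgd (-4.79 ± 0.79), Tmem100 (-4.44 ± 0.78) and Npr3 (-4.02 ± 0.44), a natriuretic peptide receptor, were among the deepest falls.

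Proliferation genes rose: 19 of 23 mitosis genes (20 adjusted over the list alone; Cdk1 2.09 ± 0.33, Mki67 1.62 ± 0.36) and 17 of 20 DNA replication genes (17; Uhrf1 2.20 ± 0.30, Mcm6 1.86 ± 0.30), with adjusted p = 0.333 and 0.308 with an estimated correlation. ERK output (14 of 17, 15 adjusted over the list alone; Dusp4 2.11 ± 0.26), alveolar type 2 (10 of 15, 11; Cebpa 1.76 ± 0.13), epithelial junction (11 of 16, 11; Krt18 2.15 ± 0.26), EGFR family (6 of 10, 6), glycolysis (7 of 11, 9), hypoxia (6 of 13, 6) and lipid-associated macrophage genes (6 of 11, 6) rose, with adjusted p from 0.299 to 0.417 with an estimated correlation. Ier3 (-0.85), Vegfa (-0.71) and Egfr (-0.29 ± 0.06) of these lists fell. p53 targets rose in 3 of 12 (2 adjusted over the list alone; camera adjusted p = 0.253), and in 1 without T790M replicate 4.

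In the same comparison markers of endothelial (19 of 20, 19 adjusted over the list alone; Tek -3.33 ± 0.54), ciliated (12 of 13, 12), alveolar type 1 (10 of 12, 10), club (5 of 12, 6), fibroblast (9 of 14, 9), smooth muscle and pericyte (10 of 12, 11) and mesothelial cells (7 of 7, 7) fell, with adjusted p from 0.299 to 0.367 with an estimated correlation. T cell (9 of 12, 9 adjusted over the list alone), NK and cytotoxic (9 of 10, 9), B cell (6 of 10, 6), neutrophil (7 of 10, 8; S100a8 -3.11 ± 0.95), adipose (4 of 5, 4) and cardiac genes (8 of 10, 9; 5 without T790M replicate 4) fell as well, with adjusted p from 0.299 to 0.424 with an estimated correlation. Alveolar macrophage genes had 1 of 13 up and 2 down (1 and 2 adjusted over the list alone; camera adjusted p = 0.980), and Marco differed by 0.80 ± 0.52 (adjusted p = 0.240). In limma 7238 genes were called, 3978 higher and 3260 lower, 1531 by at least 2-fold, and 5413 of all genes had separate ranges (29.8%, chance 0.794%), 5106 of them called. Without T790M replicate 1, the tumour nearest to the normals, the count was 7326.

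The called genes overlapped between genotypes. L858R and L858R+T790M tumours shared 2770 higher and 2324 lower genes, against 855 and 528 for independent calls, and 9 genes went opposite ways. L858R and T790M tumours shared 2758 and 2356 (926 and 589 for independent calls; 16 opposite). L858R+T790M and T790M tumours, which share their normals, had 2793 and 2393 in common (803 and 524; 3 opposite). Their log2 differences correlated across genes at r = 0.906, which are not independent replicates. Noise in the shared normals alone gave a mean r of 0.236 over 100 simulations, and with the normals split between the groups r was 0.845 to 0.895 over 20 splits. In all 3 genotypes 2325 genes were higher and 2045 lower, 338 and 716 of them by at least 2-fold in each. At the preset correlation camera called 11 lists up and 12 down in L858R tumours against their normals, and fry called 23 of these. For L858R+T790M tumours camera called 10 up and 15 down, 24 of them with fry, and for T790M tumours 10 and 16, 26 with fry. With an estimated correlation 0 of these camera calls were kept.

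**Figure D2:**
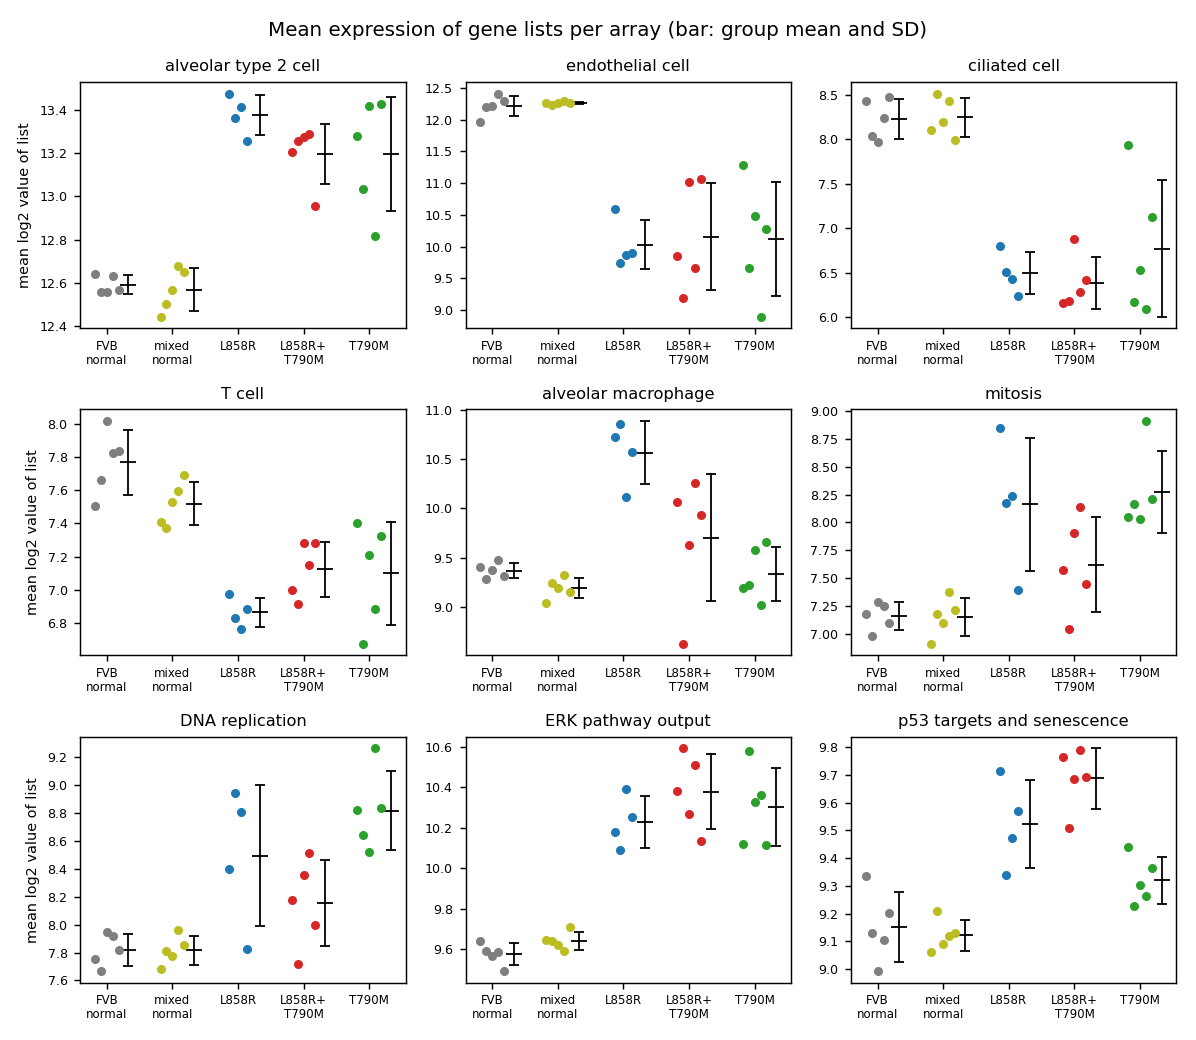
Each panel shows the mean log2 value of the measured genes of 1 list in every array, with the group mean and SD as bars, for 9 lists in 5 groups. Endothelial, ciliated and T cell means lie lower in the tumours, alveolar type 2 and ERK output means lie higher, and T790M replicate 4 has the highest mitosis mean (8.91).

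Egfr had 7 probe sets, which disagreed. The brightest, which represents the gene, differed by 0.06 ± 0.06 in L858R (adjusted p = 0.508), -0.01 ± 0.06 in L858R+T790M (adjusted p = 0.956) and -0.29 ± 0.06 in T790M tumours (adjusted p = 0.000616) against their normals. Another fell by 2.22, 1.45 and 1.68 in the same order, and with the median over the probe sets Egfr was lower in L858R tumours (-0.71, adjusted p = 0.00109). The probe sets are annotated to the mouse gene, and whether they detect the transgene was not tested.

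L858R+T790M tumours (n = 5) were compared with T790M tumours (n = 5), which asks what goes with L858R beside T790M. Ereg was 8.75-fold higher with both changes (3.13 ± 0.52, adjusted p = 0.00550), and the EGFR ligands Hbegf (1.08 ± 0.19) and Epgn (0.95 ± 0.14) were higher too. Marco (2.85 ± 0.52), the anion transporter gene Slc26a4 (2.34 ± 0.35), the glypican gene Gpc6 (1.59 ± 0.18) and Cdkn2b (1.15 ± 0.16), a cell cycle inhibitor, rose. Elapor1 (-1.62 ± 0.30), Gsta3 (-1.34 ± 0.25), a glutathione transferase, the amino acid synthesis gene Asns (-0.88 ± 0.16), the mitochondrial folate enzyme gene Aldh1l2 (-1.05 ± 0.16) and the proliferation-linked genes Cenpw (-1.15 ± 0.22) and Hmgb2 (-0.96 ± 0.17) were lower. Each of these genes kept its call whichever array was left out. Of the 37 named genes called here, 17 lost the call without some array, 16 of them without L858R+T790M replicate 1. A limma fit to these groups alone, which does not share its spread with the normal lungs, ended all 37 calls. In that fit Ereg had 3.13 ± 0.72 (adjusted p = 0.255), Marco 2.85 ± 0.61 (adjusted p = 0.239) and Gpc6 1.59 ± 0.20 (adjusted p = 0.0742).

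The EGFR family list had 4 of 10 genes up (5 adjusted over the list alone; adjusted p = 0.124 with an estimated correlation). The DNA replication list had 5 of 20 down (16 adjusted over the list alone; camera adjusted p = 3.98e-12, adjusted p = 0.303 with an estimated correlation). That count was 0 in limma, against 16 genes at an unadjusted p under 0.05 with all arrays, without L858R+T790M replicate 1, 2 or 5 or T790M replicate 1 or 4. It was 1 without T790M replicate 5, 2 without L858R+T790M replicate 3, 8 without T790M replicate 2 or 3 and 9 without L858R+T790M replicate 4. In the mitosis list limma called 0 of 23 genes (18 lower at an unadjusted p under 0.05, 17 lower adjusted over the list alone; camera adjusted p = 2.53e-09, adjusted p = 0.356 with an estimated correlation). The p53 target list had 4 of 12 up (4 adjusted over the list alone; adjusted p = 0.124 with an estimated correlation), 1 without L858R+T790M replicate 1, and 2 without L858R+T790M replicate 4 or T790M replicate 2. Hypoxia genes were called in 0 of 13 by limma (8 higher at an unadjusted p under 0.05, 6 higher adjusted over the list alone; adjusted p = 0.356 with an estimated correlation). Endothelial markers differed by a median of 0.02, with 0 of 20 called by limma and 0 at an unadjusted p under 0.05. Means of other cell type lists differed more, such as club cell (-1.12), neutrophil (0.84) and alveolar macrophage (0.37). Their exact permutation p was 0.127, 0.0714 and 0.270 (adjusted p = 0.372, 0.266 and 0.553 over 41 lists). At the preset correlation camera called 11 lists up and 6 down, and fry called 6 of these.

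In limma 289 genes were called between these groups, 139 higher and 150 lower, with 52 beyond 2-fold. Of all genes 411 had separate ranges (2.26%, chance 0.794%), 172 of them called. With each array centred on its median 159 were higher and 99 lower, and with array weights 719 genes were called (362 higher, 357 lower), 250 of the 289 among them. The count was 62 without L858R+T790M replicate 1, 151 without L858R+T790M replicate 5, 168 without T790M replicate 4, 439 without L858R+T790M replicate 2 and 485 without T790M replicate 2. Fitted to these 10 arrays alone limma called 0 genes (1857 at an unadjusted p under 0.05, lowest adjusted p = 0.0549), and 7 of 100 drawn splits of the 10 tumours called as many as the real one.

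**Figure D3:**
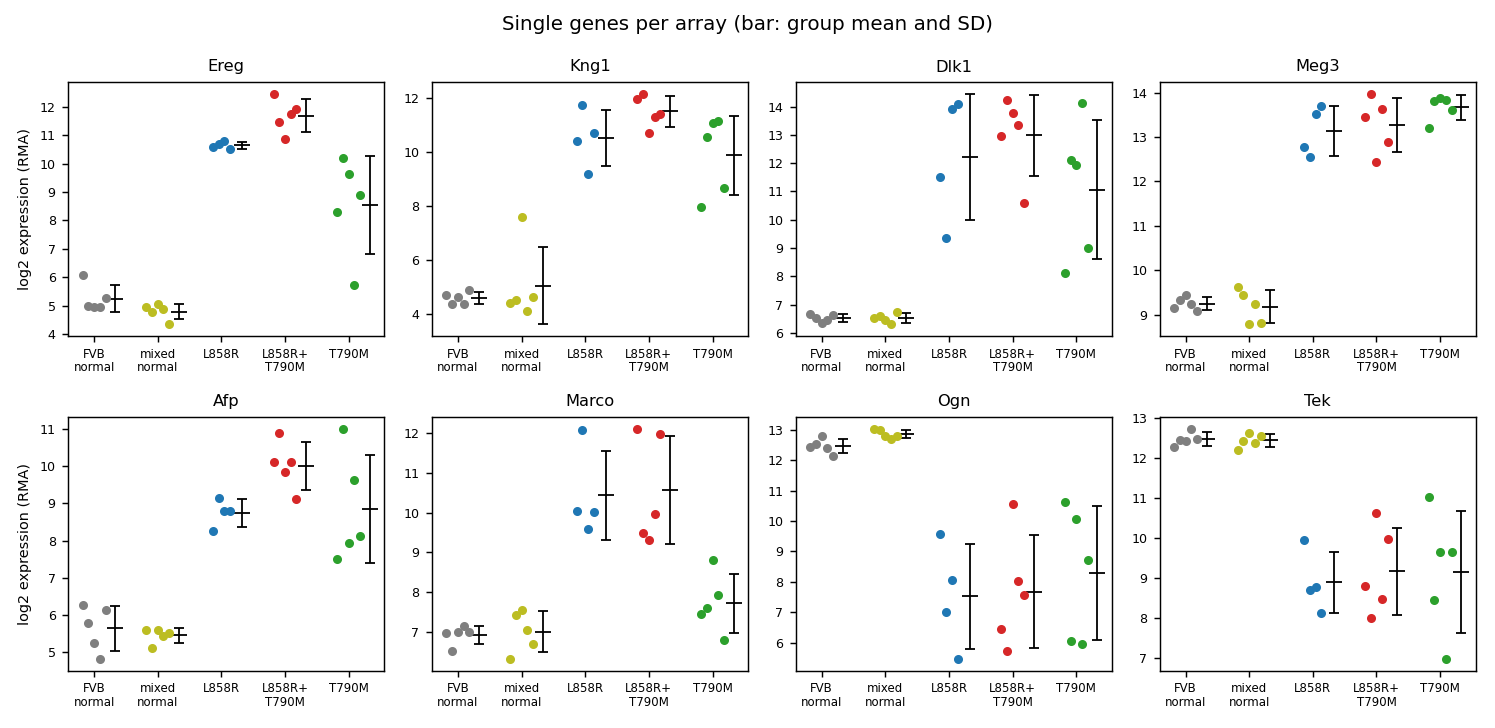
Log2 values of Ereg, Kng1, Dlk1, Meg3, Afp, Marco, Ogn and Tek in every array (points), with the mean and SD of each of the 5 groups as bars. Kng1 and Meg3 are higher and Ogn and Tek lower in the tumour groups, and Ereg in T790M replicate 4 (5.74) falls below the highest FVB normal (6.09).

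L858R tumours were compared with L858R+T790M tumours after subtraction of the matching normals (n = 4 and 5 tumours, 5 and 5 normals). The developmental transcription factor gene Eya1 (1.84 ± 0.30, adjusted p = 0.0128) and the lipase gene Lipf (1.64 ± 0.24, adjusted p = 0.00568) were higher in L858R tumours. Gpc6 (-2.08 ± 0.26, adjusted p = 0.000470) and the kinase-like gene Peak1 (-0.96 ± 0.15, adjusted p = 0.0107) were lower. Zfp874a, a zinc finger gene, had -1.40 ± 0.09, but its values differed by -0.07 between the tumours themselves and by 1.33 ± 0.06 between the normal sets. With the median over probe sets Eya1 (0.60, adjusted p = 0.210) and Gpc6 (-1.12, adjusted p = 0.0590) were not called. Of 13 alveolar macrophage genes limma called 0 (7 higher at an unadjusted p under 0.05 and 7 adjusted over the list alone; camera adjusted p = 6.77e-07, adjusted p = 0.615 with an estimated correlation). By fry 0 of the 41 lists were called in this comparison.

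In limma 13 genes were called, 7 higher and 6 lower, against 448 for the direct difference between the tumour groups, which kept 9 of the 13. With quantile normalization again 9 were higher and 13 lower. With array weights 45 genes were called (19 higher, 26 lower) and with a fit to only the groups compared 46 (24 higher, 22 lower), each with 12 of the 13. The count was 20 to 25 without L858R replicate 3 or L858R+T790M replicate 2 or 4. It was 5 to 7 without L858R replicate 1, L858R+T790M replicate 1, FVB normal replicate 1, 2, 4 or 5, or mixed-strain normal replicate 1, 3, 4 or 5. Of 100 drawn splits of the tumours, with the normals kept in place, 28 called as many.

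L858R tumours were compared with T790M tumours in the same way. Krt79, a keratin gene of the alveolar macrophage list, was higher in L858R tumours (3.19 ± 0.56, adjusted p = 0.0144), as were Ms4a8a (2.58 ± 0.49), the vesicle transport gene Rab3c (2.23 ± 0.36), Lipf (1.80 ± 0.24) and Cdkn1a (1.22 ± 0.23). Ddc, which encodes the decarboxylase that makes dopamine and serotonin (-3.92 ± 0.76), the apolipoprotein gene Apoe (-1.46 ± 0.29), the syndecan gene Sdc2 (-1.34 ± 0.21) and Asns (-1.29 ± 0.24) were lower. Between the tumours themselves Cdkn1a differed by 0.52 (adjusted p = 0.0632). Between the normal sets it differed by -0.70 (adjusted p = 0.0358), a call lost without FVB normal replicate 1 (-0.64), 2 (-0.66), 4 (-0.67) or 5 (-0.70) or mixed-strain normal replicate 1 (-0.66), 4 (-0.70) or 5 (-0.63), with adjusted p from 0.0753 to 0.0953. Of 13 alveolar macrophage genes 1 rose (9 adjusted over the list alone; adjusted p = 0.185 with an estimated correlation). In the plasma cell list 1 of 6 fell (4 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). In limma 76 genes were called, 37 higher and 39 lower; centred on array medians the split was 52 and 30. With array weights 316 genes were called (130 higher, 186 lower) and with a fit to only the groups compared 179 (103 higher, 76 lower), with 73 and 75 of the 76 among them. The count was 167 without L858R replicate 3, 145 without T790M replicate 2 and 50 without FVB normal replicate 2. The direct difference between the tumours called 1083 genes and kept 59 of the 76. Among 100 drawn splits of the tumours, with the normals kept in place, 15 called as many.

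The mixed-strain normals (n = 5) were compared with the FVB normals (n = 5), which shows how far the labelled sets of normal lung differ. The MHC class II gene H2-Eb1 was 7.13-fold higher in the mixed-strain set (2.83 ± 0.44, adjusted p = 0.00459), although mixed-strain replicate 5 (9.0) lay far from the others (11.9 to 12.5). Zfp874a (1.33 ± 0.06, adjusted p = 1.51e-11) and the clock repressor gene Nr1d1 (1.69 ± 0.30, adjusted p = 0.00846), both chosen after their values were seen, were higher too. Nkx2-1 was higher by 0.70 ± 0.13, a call lost without FVB normal replicate 5 (0.63, adjusted p = 0.0585). In the same normals camera called 5 lists up and 5 down of 41, each with adjusted p from 0.776 to 0.790 with an estimated correlation. Up were alveolar type 1 (median 0.51; limma called 0 of 12, 3 at an unadjusted p under 0.05), fibroblast (0.53; 0 of 14, 4 unadjusted), cholesterol synthesis (0.17; 0 of 14, 3 unadjusted), epithelial junction (0.17; 0 of 16, 3 unadjusted) and epithelial-mesenchymal transition genes. Down were neutrophil (-0.59; 0 of 10, 3 unadjusted), T cell (-0.21; 0 of 12, 5 unadjusted), adipose (-0.33; 0 of 5, 3 unadjusted), thymus (-0.14; 1 of 7, 3 unadjusted) and squamous or upper airway genes (-0.14; 0 of 7, 0 unadjusted). The squamous or upper airway mean was 8.44 in FVB normal replicate 1, whereas the other FVB normals (6.66 to 6.73) lay inside the mixed-strain range (6.47 to 6.77). The list means did not overlap between the sets for 3 of the 41 lists, alveolar type 1, fibroblast and epithelial-mesenchymal transition (chance: 0.794%). Endothelial markers differed by a median of 0.05 and mitosis genes by 0.01. The epithelial-mesenchymal transition list had 2 of 13 genes up (0 to 2 when each array was left out, 4 at an unadjusted p under 0.05, 3 adjusted over the list alone; adjusted p = 0.776 with an estimated correlation).

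In limma 189 genes were called between the normal sets, 123 higher and 66 lower, 14 by at least 2-fold, and 1892 of all genes had separate ranges (10.4%, chance 0.794%), 168 of them called. With a fit to only these arrays 2039 genes were called (1248 higher, 791 lower) and with array weights 3332 (1622 higher, 1710 lower), with 188 and 189 of the 189 among them. The count was 117 without FVB normal replicate 3, 80 without replicate 1, 66 without replicate 4, 57 without replicate 2 and 35 without replicate 5. Without mixed-strain normal replicate 1, 2, 4 or 5 it was 47, 70, 54 or 74. The Gapdh 3-prime minus 5-prime difference was 0.112 lower in the mixed-strain set (-0.11, exact permutation p = 0.00794, the smallest this design can give, and adjusted p = 0.0794 over 10 tests), and that of actin -0.07 (p = 0.159).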

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

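The tests of linked strain variants, time of day, RNA quality, a mislabelled lung and T790M replicate 4, and the exact tests of all list means, were chosen only after the results they concern had been seen. The predictions for normal tissue in the nodule, tumour content, sex and other splits of the arrays are recorded as written beforehand. All of these but the splits concern patterns that were themselves found in these data.

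The normal sets differed in 189 genes. Strain variants in linked blocks stay open. Of the called genes 8 had a called gene within 2 neighbours on either side, as in random gene sets (median 8, gene order of GRCm38). At least as many were found in 540 of 1000 random sets. The count that linked blocks would give was not computed, so this match cannot argue against them. A time of day at harvest that differed between the sets is a candidate explanation: with Nr1d1 itself left out, clock genes of its phase were higher in the mixed-strain set (median 0.539) and those of the Bmal1 phase were lower (-0.88), although limma called 0 of 8 and 0 of 5 of them (4 and 2 at an unadjusted p under 0.05), and the difference between these list means was 2.86 ± 0.29 (SD, n = 5) against 1.61 ± 0.50 (n = 5; exact permutation p = 0.00794, the smallest this design can give, adjusted p = 0.0833 over 42 tests). RNA quality or a labelling batch cannot be told apart from the groups, because the Gapdh 3-prime minus 5-prime difference (-0.11, exact permutation p = 0.00794, adjusted p = 0.0794 over 10 tests) separated the sets in every array, although that of actin did not (-0.07, p = 0.159, 2 FVB normals inside the mixed-strain range), and the labels give no batch. Among the called genes 140 of 189 (74.1%) differed the same way between the tumours of the same labels, with a slope of 0.28, 12 of them by more than 0.5. These tumours differ in genotype too, and the share over all genes was not computed, so this decides nothing on strain. A strain effect outside linked blocks was not tested and stays open too.

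T790M replicate 1 lay between the other tumours and the normal lungs. A mislabelled normal lung is argued against, since Ereg, Kng1 and Meg3 were 2.20, 3.08 and 3.76 above the highest FVB normal, although only 0.38 for Kng1 above the highest of all 10 normals (2.20 and 3.59 for Ereg and Meg3), and since 94 of the 113 genes below lay above every normal lung, against 2 to 26 in any normal lung. Normal lung tissue in the dissected nodule is a candidate explanation: its share came to 0.501 from 113 genes that are higher in the other T790M tumours and to 0.373 from 333 that are lower. The other T790M tumours gave -0.39 to 0.35 and -0.13 to 0.07. A tumour that differs from the others in its own expression was not tested.

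Mitosis and DNA replication list means were lower in L858R+T790M than in T790M tumours, by -0.65 (exact permutation p = 0.0238, adjusted p = 0.163 over 41 lists) and -0.66 (p = 0.00794, adjusted p = 0.0813, although 0.00794 is the smallest p this design can give and passes only if 7 lists share it, where 4 did), and with camera at an estimated correlation the adjusted p was 0.356 and 0.303. Lower tumour content stays open. A set of 115 genes at least 4-fold higher in L858R tumours than in their normals had a median difference of 0.25 (quartiles -0.11 and 0.76). That median was 0.08 to 0.32 when each array was left out, where lower content alone would give a negative one. The set was chosen in tumours with L858R, which T790M tumours lack, so a genotype effect could raise it whatever the content. Sex is argued against, since the mitosis difference was -0.64 with the sex score as a covariate (99.4% kept). A strongly proliferating T790M replicate 4 stays open, since without it the mitosis difference was -0.49 (75.3% kept) and that of DNA replication -0.55 (83.1% kept). The genotype stays open beside it, as no test here separates a genotype effect from a few fast-growing tumours.

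Splits of the same arrays into groups of the same sizes were used to ask whether chance could give as many calls. For each comparison 100 of 126 splits were drawn. The splits argue against chance for L858R against mixed-strain normals (7523 genes, highest other split 5053). They also do so for L858R+T790M (6594, highest other 2410) and T790M tumours against FVB normals (7238, highest other 3200), and for the normal sets (189, highest other 1). In each of these comparisons 1 of 100 splits, the real one, called as many. Chance is not excluded, since not every split was drawn and 126 are few. No such argument holds for L858R+T790M against T790M tumours (289 genes, 7 of 100 splits, highest other 1538), where chance cannot be excluded. For L858R against L858R+T790M (13, 28 of 100, highest other 1392) and against T790M tumours (76, 15 of 100, highest other 1193) only tumours were exchanged. The normal sets, which differ, kept their places. These splits therefore cannot decide on chance for the difference between tumour effects, and chance stays open there. Splits that called so many genes point to a structure of the samples. The split with 1538 put L858R+T790M replicates 1, 2 and 4 with T790M replicates 2 and 4, the tumours at 40.3 or above on the first principal component. The split with 5053 put mixed-strain replicate 4 with the L858R tumours, and those with 2410 and 3200 exchanged 1 FVB normal for 1 tumour.

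Single arrays lay far from the rest of their group by Dixon's test in 18 of 488 gene groups and 2 of 45 list groups, where chance gives about 1 in 20. In FVB normals these were Egln3 (7.86) and Ereg (6.09) in replicate 1, Marco (6.52) in replicate 2, Tmem100 (12.68) in replicate 4 and Ddit3 (9.38) in replicate 5. In mixed-strain normals they were Kng1 (7.58) in replicate 3, Mamdc2 (11.38) and Gpam (11.77) in replicate 4 and H2-Eb1 (9.0) in replicate 5. In L858R tumours they were Cidec (5.87) and Gpam (9.78) in replicate 1. In L858R+T790M tumours they were Krt19 (12.69) in replicate 1, Hbegf (9.89), Mki67 (6.96) and Trib3 (9.81) in replicate 2, and the alveolar type 2 list mean (12.95) in replicate 5. In T790M tumours they were Ms4a8a (5.40) and Npr3 (8.92) in replicate 1, Pkm (12.13) in replicate 2 and the mitosis list mean (8.91) in replicate 4. The remaining lists were not tested, so more list means may stand apart. FVB normal replicate 1 had a squamous or upper airway mean of 8.44, against 6.66 to 6.73 in the other FVB normals. Its skeletal muscle mean was 8.38, against 6.21 to 6.42 in the other FVB normals. Foreign tissue in this lung was not tested.

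The tumour effects of L858R and L858R+T790M differed in 13 genes by the test of the difference itself. Higher in L858R were Cd200r4 (3.18), Slc15a2 (1.96), Eya1 (1.84), Lipf (1.64), Dhrs3 (1.08), Scpep1 (0.83) and Nrg4 (0.65), and lower were Gpc6 (-2.08), Zfp874a (-1.40), Tmem119 (-1.12), Fam114a1 (-1.10), Peak1 (-0.96) and Sybu (-0.62). Of these, 8 lost the call without at least 1 of the arrays, whereas Eya1, Lipf, Gpc6, Zfp874a and Peak1 kept it. Cd200r4, Eya1, Lipf, Nrg4, Zfp874a and Sybu were among the 6064 dimmest genes. With the median over probe sets Slc15a2 (0.71, adjusted p = 0.553), Eya1 (0.60, 0.210), Scpep1 (0.63, 0.0590), Nrg4 (0.43, 0.230), Gpc6 (-1.12, 0.0590) and Fam114a1 (-0.82, 0.0590) were not called, and in the direct difference Slc15a2 (0.71, 0.136), Zfp874a (-0.07, 0.606), Tmem119 (-0.54, 0.0561) and Sybu (-0.27, 0.0829) were not. Calls also ended for Sybu with median centring, for Cd200r4 with array weights and with only the groups compared, and for Cd200r4, Scpep1, Nrg4 and Sybu with the sex score.

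The effects of L858R and T790M differed in 76 genes. Named here and higher in L858R were Krt79 (3.19), Wfdc21 (3.04), Cd200r4 (3.01), Ms4a8a (2.58), Acot1 (2.34), Rab3c (2.23), Vstm2a (2.09), Slc15a2 (1.90), Lipf (1.80), Eya1 (1.57), Ltc4s (1.53), Rab27b (1.44) and Cdkn1a (1.22). Lower were Ddc (-3.92), Pcdh18 (-1.46), Apoe (-1.46), Sdc2 (-1.34), Asns (-1.29), Zfp874a (-1.29), Dact1 (-1.23) and Hpse (-1.22). Of these, 7 lost the call without at least 1 array: Wfdc21, Cd200r4, Acot1, Ltc4s, Pcdh18, Dact1 and Hpse. Cd200r4, Ms4a8a, Vstm2a, Lipf, Eya1 and Zfp874a were among the 6064 dimmest genes. With the median over probe sets Slc15a2 (0.86, adjusted p = 0.280) and Eya1 (0.73, 0.0631) were not called, nor were Slc15a2 (0.64, 0.131), Cdkn1a (0.52, 0.0632) and Zfp874a, which changed sign (0.0375, 0.785), in the direct difference. Calls also ended for Hpse with quantile normalization and for Cd200r4 and Ltc4s with array weights.

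The 10092 probe sets with no gene or several genes, outside the gene tests, also held calls. They numbered 2939 for L858R, 2191 for L858R+T790M and 2630 for T790M tumours against their normals, 69 for L858R+T790M against T790M, 15 and 29 for L858R against these groups after strain adjustment, and 295 between the normal sets.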

How the results depend on the processing

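List counts without each array and under both scalings were alternatives chosen only after the data were seen. The counts of the 3 tumour groups against their normals stayed within 1.5 times the reported value under every alternative except the ones named here, and every list with a camera call kept its direction under both scalings. The cause was not tested for any change below unless one is given. Without the 6064 dimmest genes the counts went both ways: 7 for L858R against L858R+T790M and 123 between the normal sets were lower, and 354 for L858R+T790M and 82 for L858R against T790M were higher. All 7 and all 123 were among the reported calls. For L858R against L858R+T790M the count fell because Cd200r4, Eya1, Lipf, Nrg4, Zfp874a and Sybu were among the genes dropped.

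In the order L858R, L858R+T790M and T790M tumours against normals, L858R+T790M against T790M, L858R against L858R+T790M and against T790M, and the normal sets, testing every probe set gave 16816, 13855, 15675, 517, 77, 185 and 1117. Requiring a 2-fold change gave 1966, 1536, 1531 and 52 for the first comparisons, 34 for L858R against T790M and 14 between the normal sets, by construction. At an adjusted p under 0.01, L858R+T790M against T790M gave 45, the normal sets 23, and L858R against L858R+T790M and T790M 3 and 2, by construction. Median centring gave 102 between the normal sets, and quantile normalization gave 22 for L858R against L858R+T790M and 125 between the normal sets. Array weights gave 719, 45, 316 and 3332 for the last 4 comparisons, and a fit to only the groups compared gave 0, 46, 179 and 2039. For the 0, limma had 1857 genes at an unadjusted p under 0.05. The direct difference between tumour groups gave 448 and 1083. The sex score gave 124 for L858R against T790M.

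The replicate number used as a block gave 187 for L858R+T790M against T790M, 8 for L858R against L858R+T790M and 115 between the normal sets. With the block 20 of 244 called values of named genes lost their call, 9 of them between L858R+T790M and T790M tumours, 6 and 4 between L858R and these groups and 1 (Pfkp) between L858R and its normals. With the block limma called 0 of 20 DNA replication genes lower in L858R+T790M than in T790M (16 at an unadjusted p under 0.05, lowest adjusted p = 0.0571). In these groups 4 of 5 like-numbered arrays correlated over 0.1 (0.0029 to 0.44), but only 2 of 5 L858R+T790M arrays correlated best with their own number.

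Of 244 called values of named genes, 3 lost their call with median centring, 3 with quantile normalization, 15 with the median over probe sets, 6 with array weights, 41 with only the groups compared, 7 with the sex score, 62 at an adjusted p under 0.01 and 38 with a 2-fold change. In the direct difference 7 of the 34 values it covers lost their call, and with all normal lungs as 1 group 2 of 167 did. Leaving out each array gave 6735 to 7581, 5834 to 6706, 6514 to 7326, 62 to 485, 5 to 25, 50 to 167 and 35 to 203 in the same order. With the median over probe sets Sftpc (-0.37, adjusted p = 0.00721) and Egfr (-0.71, adjusted p = 0.00109) were lower in L858R tumours, opposite in sign to the reported values. Zfp874a was 0.0375 (adjusted p = 0.785) in the direct difference of L858R and T790M tumours, since that setting leaves out the normal sets, which differ in this gene.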

Other observations

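The test of the Dlk1-Dio3 cluster was chosen only after Dlk1, Meg3, Rian and Mirg had been seen among the most changed genes.

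Other fixed lists moved in parts. Genes of the immediate early stress response fell in 5 of 13 and rose in 1 in L858R+T790M (5 and 1 adjusted over the list alone) and fell in 6 and rose in 1 in T790M tumours (6 and 1), with adjusted p = 0.508 and 0.362 with an estimated correlation. The heat shock gene Hspa1a (-3.58 and -3.08) and the transcription factor gene Klf4 (-2.31 and -2.29) were among those that fell, and Junb (0.74 and 0.51) rose, in T790M tumours with no call without FVB normal replicate 4 (0.42, adjusted p = 0.0583). Of the epithelial-mesenchymal transition genes 8, 6 and 7 of 13 fell and 0, 1 and 1 rose by limma in L858R, L858R+T790M and T790M tumours (8, 6 and 7 fell and 2, 2 and 1 rose adjusted over the list alone), with Zeb1 at -2.43, -2.05 and -2.04 and adjusted p = 0.296, 0.464 and 0.367 with an estimated correlation. Fatty acid synthesis genes rose in 6, 7 and 6 of 12 and fell in 1, 2 and 1 (6, 7 and 8 rose and 1, 2 and 2 fell adjusted over the list alone; adjusted p = 0.337, 0.385 and 0.308 with an estimated correlation), with Me1, a source of NADPH, at 2.06, 2.02 and 1.77, while Gpam fell (-1.30, -1.61 and -1.12).

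Of the distal lung progenitor and fetal list 2, 4 and 5 of 11 rose and 1, 2 and 1 fell (2, 5 and 5 rose and 1, 2 and 2 fell adjusted over the list alone; camera adjusted p = 0.888, 0.402 and 0.343), with Sox2, a gene of the conducting airway, at -3.48 in L858R+T790M. The T790M count was 3 without T790M replicate 4 or FVB normal replicate 2 or 5. In the unfolded protein response list Trib3 rose in each tumour group (0.92, 1.24 and 1.74), and 3, 3 and 5 of 12 genes rose while Ddit3 fell (-0.91, -0.86 and -0.64; camera adjusted p = 0.762, 0.848 and 0.0698). Dendritic cell and MHC class II genes fell in 5, 5 and 2 of 11 (5, 5 and 3 adjusted over the list alone; camera adjusted p = 0.174, 0.0994 and 0.979), while 1, 0 and 4 rose (2, 0 and 4 over the list alone), in T790M tumours among them Ciita (1.03) and H2-Eb1 (1.81), which was not called against all 10 normals (0.39, adjusted p = 0.659).

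Dlk1, Meg3, Rian and Mirg lie in the imprinted Dlk1-Dio3 cluster. All 4 measured members were called higher in each of the 3 tumour groups, but this decides nothing on a shared rise of the Dlk1-Dio3 imprinted cluster, since each of the 4 had been picked for its rise. The medians of 4 flanking genes were -0.30, -0.28 and -0.34 in L858R, L858R+T790M and T790M tumours.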
